A study of Mus musculus with 19 samples.

How the data were processed

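Samples were grouped by the genotype of the tumour cells given in the labels. The groups were input RNA and ribosome footprints of cultured SCR and KO cells (2 libraries each), TCRβ sequences from blood of mice with SCR (4) or KO tumours (5), and CD45-positive tumour cells (1 library each). Count columns named POOL were taken as KO by elimination, since the other columns are named SCR, and the single-cell library named WT was taken as SCR. Per the labels, footprints were made from cells treated with cycloheximide (100 µg/ml, 8 min) and digested with RNase for 40 min at 22 C. The labels do not say whether replicate numbers pair libraries of different groups. Deviations from the group mean of the SCR and KO libraries of the same number correlated across genes with an r of 0.0592 in input RNA and 0.0666 in footprints. Between footprints and input RNA of replicate 1, r was -0.0144 in SCR and -0.0277 in KO cells. With 2 libraries per group these values cannot exclude pairing, and the main fits treated the libraries as unpaired.

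Expected counts per gene and library were deposited by the authors as whole numbers and were not normalized. Per the submitters' processing notes the tools were STAR 2.7.10a and StringTie 2.1.7 on GRCm39, with no role or order stated. The authors' table of translational efficiency holds a ratio of footprints to input RNA per genotype, its log2 fold change and a p-value with its adjusted form; the tool that made these values is not given in the sources used here. For each listed nuORF the authors deposited a count of P-sites per reading frame, an RPKM, read here as covering all libraries together, and an adjusted p-value of its translation. The ORF caller is not given in the sources used here. Per the file headers, each mouse has a count of reads and a fraction of all reads for each clonotype, and a fraction for each pair of V and J genes; the clonotype caller is not given in the sources used here. Single-cell UMI counts per gene and cell came from Cell Ranger 8.0.1, per the file headers.

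The comparisons, tests, filters, gene lists, rule for naming genes and most alternative settings were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16, with TMM scaling, filtering by expression, a dispersion trend and a quasi-likelihood F test, at a Benjamini-Hochberg adjusted p below 0.05. Input RNA and footprints were fitted apart, and translational efficiency as the interaction of genotype and assay over all 8 libraries, which therefore shares its libraries with both. All log2 fold changes are KO minus SCR and their SE comes from the fit. The 23 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 23 lists of a comparison, again with the correlation estimated from the data, and with fry. Counts of members were made over all genes tested and adjusted over the list alone. DESeq2 1.42.0 and limma's voom were alternative tools. In simulated data with 200 changed genes, edgeR found 73% of genes at a log2 fold change of 1 and 98% at 2 in input RNA, 77 and 96% in footprints and 54 and 75% in translational efficiency, with 2.81 to 5.15% false calls. With a spread of its own for each gene, the false calls were 12.8% in input RNA, 20.3% in footprints and 10.7% in translational efficiency.

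Mettl5 was named first. In each comparison the 10 largest rises and 10 largest falls were named among genes past the threshold, with a fitted mean of at least 4 log2 CPM, both KO libraries on the same side of both SCR libraries and no name of a predicted gene. In each list up to 4 members past the threshold were named by smallest p, and otherwise up to 2 as values. For TCRβ the V and J genes past the threshold, or the 4 of smallest p, and the largest clonotype of each mouse were named. For single cells the 5 largest and 5 smallest ratios and up to 4 members per list were named, in classes of at least 100 cells in both libraries and for genes of at least 100 UMIs. Not every gene that the rule allows is named. Genes that changed in both assays, Trmt112 as the partner of Mettl5, and genes used as markers of other cells were also named, some of them after their values were seen. The rule for nuORFs used TPM, which was not used here, so the 5 of highest RPKM per list were named.

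Clonotypes were as the authors listed them, each mouse thinned to the lowest read total. Differences of group means were tested two-sided with exact permutation tests over all splits of the 9 mice, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. V and J genes of at least 0.5% mean share were tested likewise and with limma. At least 4 genes at the smallest p are needed before any passes, so 1 gene alone cannot. In 20 simulated runs, 92% of 100 changes of 1.5-fold, several per run, were found. PCR reads without molecular identifiers are not independent molecules.

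Cells with at least 500 UMIs, at least 300 genes and under 10% mitochondrial UMIs were kept, 8239 of 8341 (SCR) and 8360 of 8454 (KO), with genes seen in at least 10 cells. With scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and scikit-learn 1.9.0, counts were scaled to 10000 per cell, and 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1 gave the clusters. Clusters were named from fixed marker lists, and clusters that met no list stayed unnamed. Shares have exact Clopper-Pearson 95% intervals, and summed counts per class exact Poisson 95% intervals, which cover counting error only; a count of 0 allows up to 3 counts. The 13 gene lists were set against 10000 random lists matched on expression, with percentiles below 2.5 or above 97.5 called apart. In simulated data 10 of 10 lists shifted by 0.3 and 0 of 10 unshifted lists passed. The simulation had counting error alone and lists of genes drawn independently among those of at least 500 UMIs. It does not show how often lists of co-expressed genes pass between libraries by other differences than genotype. Figures were drawn with matplotlib 3.10.9.

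Alternatives were other scalings, filters, thresholds, tools and a replicate block for counts, other weights, units and depths for TCRβ, other cell filters, resolutions and doublet handling for single cells, and leaving out each replicate. The full ORF catalogue was used only for counts by type.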

Results

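Ribosome profiling and input RNA sequencing of cultured cells, T-cell receptor beta (TCRβ) sequencing of blood and single-cell RNA sequencing of tumours were compared between cells with a Mettl5 knockout (KO) and cells with a scrambled control (SCR). The cells were B16-F10, a melanoma line of C57BL/6 mice. METTL5 is a methyltransferase of the RNA of the small ribosomal subunit and works as a complex with TRMT112. The 19 samples were 8 libraries of cultured cells (2 per genotype and assay), the blood of 9 mice and 2 single-cell libraries of CD45-positive cells sorted from tumours (1 per genotype). Blood was taken 12 days after inoculation with SCR (4 mice) or KO cells (5 mice). Total gene counts per library were 38968000 to 48692578 in input RNA and 14555963 (KO) to 31301806 (SCR) in footprints. There were 5277004 to 6912106 TCRβ reads per mouse, and medians of 8906 (SCR) and 8034.5 (KO) UMIs per cell. The labels do not say that replicate libraries came from separate cultures, so the p-values for cultured cells measure only the spread between these libraries.

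Mettl5 itself had 369 and 414 counts in SCR and 303 and 268 in KO input RNA. Scaled to the same library total (CPM), these were 9.47 and 9.61 against 6.22 and 6.15. The transcript fell in KO cells (log2 fold change -0.56, SE 0.13, adjusted p = 0.0284). Footprints were 14.6 and 13.2 in SCR and 11.5 and 12.0 CPM in KO cells (log2 fold change -0.35, SE 0.09, adjusted p = 0.112). The counts cover the whole gene and the labels do not give the edit, so they check the knockout only in part. An edit that shifts the reading frame need not remove the RNA. Footprints per RNA did not fall (authors' values 0.871 in SCR and 0.968 in KO cells).

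Input RNA showed which transcripts differed between KO and SCR cells in culture (2 libraries per genotype). Of 20025 genes tested, 1915 rose and 1443 fell in KO cells. Among well expressed genes, the largest rises were in Zc3h10, a zinc finger gene (log2 fold change 1.78, SE 0.13, adjusted p = 0.00120), Enpp2, which encodes the lysophospholipase autotaxin (1.70, SE 0.05, adjusted p = 7.00e-05), and Col1a2, a chain of type I collagen (1.499, SE 0.10, adjusted p = 0.000686). The largest falls were in Postn, a secreted matrix protein (-2.84, SE 0.10, adjusted p = 0.000105), Mgll, which encodes monoacylglycerol lipase (-1.47, SE 0.09, adjusted p = 0.000436), and the type IV collagen gene Col4a1 (-1.30, SE 0.05, adjusted p = 0.000105). Enpp2 was at 39.3 and 39.8 CPM in SCR and 123 and 122 CPM in KO cells, and Postn at 33.9 and 34.8 against 4.27 and 4.91 CPM. The other large rises were Lrch4 (1.32), Rgs7bp (1.18), Bfsp2 (1.13), Zfp469 (1.12), Fkbp6 (1.04), Gcsh (1.02) and the histone gene H2ac18 (0.99). The other large falls were Rnasek (-1.26), the connexin gene Gjb2 (-1.19), Ahnak (-1.13), S100a11 (-1.13), the copper carrier ceruloplasmin Cp (-1.10), Dtna (-1.10) and Col4a2 (-1.09). The count of changed genes, 3358, was 1031 without SCR replicate 1 and 1417 without SCR replicate 2, and 1193 when no genes were filtered out.

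Genes of antigen presentation and of the interferon response were lower in KO input RNA. Of 16 measured genes of MHC class I antigen presentation, 6 fell and 2 rose (median log2 fold change -0.28, camera adjusted p = 0.00153, and adjusted p = 0.343 with an estimated correlation). Adjusted over the list alone, 6 fell and 2 rose as well. The peptide transporter genes Tap2 (-2.95, SE 0.28, adjusted p = 0.00238) and Tap1 (-1.60, SE 0.21, adjusted p = 0.00537), the class I heavy chain gene H2-K1 (-1.26, SE 0.20, adjusted p = 0.00981) and its light chain gene B2m (-0.49, SE 0.05, adjusted p = 0.00349) fell. Tap2 was at 3.54 and 2.99 CPM in SCR and 0.472 and 0.321 CPM in KO cells. Of 33 interferon-stimulated genes, 8 fell and 1 rose, by all genes and adjusted over the list alone. The list median was -0.21 (camera adjusted p = 0.00263, and adjusted p = 0.343 with an estimated correlation). They included the RNA sensor gene Ddx58 (-0.84, SE 0.12), Dtx3l (-0.89, SE 0.11) and Parp14 (-0.82, SE 0.15). Among 18 genes of tumour-cell ligands for T and myeloid cells, 4 fell and 1 rose, and 5 fell and 2 rose adjusted over the list alone (median -0.15, camera adjusted p = 0.0627). Lgals3, which encodes galectin 3, fell (-3.22, SE 0.17, adjusted p = 0.000361), as did Cd274, which encodes PD-L1 (-0.94, SE 0.12, adjusted p = 0.00568), and the NKG2D ligand gene Ulbp1 (-1.03, SE 0.23, adjusted p = 0.0255), while Tgfb1 rose (1.36, SE 0.24, adjusted p = 0.0131). The H2 genes are close paralogs, and reads shared between them could have been split.

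Transcripts of the translation machinery were higher in KO input RNA. Of 34 small and 48 large ribosomal subunit protein genes, 30 and 40 rose and none fell. Both medians were 0.37 (camera adjusted p = 6.55e-20 and 5.71e-23, and adjusted p = 0.343 for each with an estimated correlation). Adjusted over the list alone, 33 and 44 rose and 0 and 2 fell. Examples were Rps29 (0.44, SE 0.06), Rps12 (0.76, SE 0.11), Rpl13 (0.65, SE 0.06) and Rpl6 (0.44, SE 0.05). Of 45 initiation factor genes, 18 rose and none fell, such as Eif3b (0.48, SE 0.05) and Eif4h (0.48, SE 0.06). Adjusted over the list alone 27 rose, with a median of 0.18 (camera adjusted p = 2.92e-08, and adjusted p = 0.343 with an estimated correlation). Among 16 elongation and termination factor genes, 7 rose, Eef1a1 among them (0.33, SE 0.05), and 1 fell, and 10 rose and 1 fell adjusted over the list alone. The list's median was 0.17 (camera adjusted p = 0.000148, and adjusted p = 0.343 with an estimated correlation). Of 38 genes of rRNA modification and small subunit biogenesis, 21 rose and 1 fell, and 29 rose and 1 fell adjusted over the list alone. The members' median was 0.28 (camera adjusted p = 2.48e-11, and adjusted p = 0.343 with an estimated correlation). Trmt112, the partner of Mettl5, rose in this list (0.80, SE 0.10, adjusted p = 0.00527), as did the rRNA methyltransferase gene Fbl (0.45, SE 0.06, adjusted p = 0.00513). Of 30 genes of the ATF4 and integrated stress response, 14 rose and none fell, and 16 rose adjusted over the list alone, with a median of 0.22 (camera adjusted p = 7.66e-07, and adjusted p = 0.343 with an estimated correlation). Atf4 rose by 0.52 and the amino acid transporter gene Slc7a5 by 0.48 on the log2 scale. Of 18 nonsense-mediated decay factor genes, 5 rose and none fell, 6 adjusted over the list alone, with Upf1 at 0.44, SE 0.05. The median over members was 0.10 (camera adjusted p = 0.00464, and adjusted p = 0.343 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, which the counting could have mixed with the parent genes.

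Transcripts of replication, protein turnover and respiration were also higher in KO input RNA, and those of hypoxia and cholesterol synthesis lower. Of 38 replication-dependent histone genes, 30 rose and none fell, 33 adjusted over the list alone, among them H4c8 (0.81, SE 0.10) and H3c6 (0.51, SE 0.05). The histone median was 0.55 (camera adjusted p = 5.71e-23, and adjusted p = 0.343 with an estimated correlation); copies of histone genes are near identical. Of 44 genes of DNA replication, 19 rose and none fell, 25 adjusted over the list alone, with the licensing factor gene Cdt1 at 0.54, SE 0.07. The median was 0.20 (camera adjusted p = 4.21e-08, and adjusted p = 0.343 with an estimated correlation). Of 37 proteasome genes, 20 rose and none fell, 30 adjusted over the list alone, for example Psmd7 (0.51, SE 0.07). The list median was 0.29 (camera adjusted p = 6.42e-11, and adjusted p = 0.362 with an estimated correlation). Of 73 nuclear genes of oxidative phosphorylation, 32 rose and none fell, and adjusted over the list alone 50 rose and 1 fell, with Cox4i1 at 0.74, SE 0.11. The median was 0.27 (camera adjusted p = 4.09e-11, and adjusted p = 0.387 with an estimated correlation). Of 13 mitochondrially encoded genes only mt-Co3 passed and fell (-0.42, SE 0.11), none adjusted over the list alone. The list's median was -0.27 (camera adjusted p = 0.0136, and adjusted p = 0.602 with an estimated correlation). Of 26 genes of glycolysis and hypoxia, 9 fell and none rose, with the same counts adjusted over the list alone. The list median was -0.08 (camera adjusted p = 0.00051, and adjusted p = 0.387 with an estimated correlation). The hypoxia-induced genes Adm (-2.03, SE 0.20), Bnip3 (-0.74, SE 0.11) and Pdk1 (-0.73, SE 0.07) were among them. Of 24 cholesterol synthesis genes, 3 fell, as they did adjusted over the list alone: Nsdhl (-0.52, SE 0.08), Hmgcs1 (-0.28, SE 0.05) and Tm7sf2 (-0.60, SE 0.15). The members' median was -0.08 (camera adjusted p = 0.034, and adjusted p = 0.511 with an estimated correlation).

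The other lists did not pass in input RNA. Melanocyte genes went both ways, 6 up and 7 down of 22, and 7 up and 8 down adjusted over the list alone (median -0.03, camera adjusted p = 0.553). The melanosome antigen gene Mlana (0.59, SE 0.08) and Dct (0.43, SE 0.04) rose, and the melanosome channel gene Oca2 (-1.68, SE 0.15) and the receptor gene Kit (-0.61, SE 0.07) fell. Of 22 p53 targets 6 rose and 4 fell, and 8 and 5 adjusted over the list alone, and Eda2r fell (-1.37, SE 0.14). Their median was 0.07 (-0.02 with the size factors of DESeq2) while the mean was -0.05 (camera adjusted p = 0.997). Of 24 genes of the unfolded protein response 2 rose and 2 fell, 2 and 4 adjusted over the list alone, with Atf6 at -0.99, SE 0.06. The median was 0.03 and the mean -0.01 (camera adjusted p = 0.473). Of 36 mitosis genes 4 rose and 2 fell, also adjusted over the list alone (median -0.00 and mean 0.01, camera adjusted p = 0.798), with Cenpa at 0.29, SE 0.05 and Anln at -0.23, SE 0.05. None of 6 markers of blood cells passed (median -0.39, camera adjusted p = 0.389); Cd68 was at -0.60 (adjusted p = 0.238). Of 8 markers of fibroblasts and endothelium, 2 rose and 2 fell, with the same counts adjusted over the list alone (median -0.19, camera adjusted p = 0.0627). Col1a2 and Pdgfra (0.53, SE 0.14) rose, and Postn and Col3a1, which had 16 and 17 counts in SCR and 0 and 0 in KO cells, fell. Fry tests whether a set's genes move on balance in 1 direction and compares them with no other genes. By fry 7 lists passed in input RNA, each at an adjusted p of 0.0477. They were MHC class I, interferon-stimulated genes, initiation factors, rRNA modification, DNA replication, nonsense-mediated decay and the fibroblast markers.

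Ribosome footprints showed which genes had more or less ribosome occupancy in KO cells (2 libraries per genotype). Of 16878 genes tested, 86 rose and 301 fell. The largest rises among well expressed genes were in Pla2g4a, a cytosolic phospholipase (log2 fold change 1.18, SE 0.08, adjusted p = 0.0170), the laminin gene Lamb1 (1.09, SE 0.08, adjusted p = 0.0195) and Dcaf8l (0.98, SE 0.07, adjusted p = 0.0195). They were followed by Gsdmc (0.92), Enpp2 (0.84), Ddx58 (0.74), Dusp6 (0.72), the chemokine gene Cxcl10 (0.71), Npnt (0.70) and Mest (0.69). The largest falls were in the matrix gene Thbs2 (-3.52, SE 0.22, adjusted p = 0.0155), the zinc transporter gene Slc39a7 (-2.20, SE 0.23, adjusted p = 0.0319) and Postn (-1.88, SE 0.12, adjusted p = 0.0155). Next came Cubn (-1.82), Tap2 (-1.78), Col4a2 (-1.71), Hapln1 (-1.69), Aqp4 (-1.66), Cited1 (-1.66) and Abca8a (-1.60). Thbs2 had 794 and 1046 footprint counts in SCR and 52 and 50 in KO cells. With 387 changed genes in the full data, 128 passed without SCR replicate 1, 44 without SCR replicate 2, 25 without KO replicate 1 and 57 without KO replicate 2, and DESeq2 called 1207.

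In footprints, MHC class I genes were lower and interferon-stimulated genes higher as sets. Of 16 measured MHC class I genes 4 fell and none rose, also adjusted over the list alone: Tap2 (-1.78, SE 0.07), Tap1 (-0.79, SE 0.07), the peptide-loading chaperone gene Tapbp (-0.96, SE 0.05) and H2-K1 (-0.76, SE 0.08). The median over members was -0.11 (camera adjusted p = 0.000401, and adjusted p = 0.524 with an estimated correlation). Of 35 interferon-stimulated genes 3 rose, namely Cxcl10, Ddx58 and Ifit3b (1.14, SE 0.14), and none fell, and 11 rose adjusted over the list alone. The median was 0.38 (camera adjusted p = 1.46e-07, and adjusted p = 0.524 with an estimated correlation). Among 22 melanocyte genes Kit (-1.20, SE 0.10) and Oca2 (-0.95, SE 0.09) fell, and 1 rose and 6 fell adjusted over the list alone. The list's median was -0.09 (camera adjusted p = 0.00449, and adjusted p = 0.524 with an estimated correlation). Among 23 p53 targets the cell-cycle inhibitor gene Cdkn1a (-0.58, SE 0.06), Eda2r (-1.03, SE 0.11) and Ephx1 (-0.58, SE 0.07) fell and Ckap2 rose (0.43, SE 0.06), and 9 fell and 1 rose adjusted over the list alone. The members' median was -0.23 (camera adjusted p = 0.000282, and adjusted p = 0.524 with an estimated correlation). Among 23 genes of the unfolded protein response the sensor genes Atf6 (-0.78, SE 0.08) and Ern1 (-0.56, SE 0.08) fell, and 9 fell and 1 rose adjusted over the list alone. The median over members was -0.16 (camera adjusted p = 0.000524, and adjusted p = 0.573 with an estimated correlation). Of 34 small ribosomal subunit genes only Rps29 passed (-0.57, SE 0.06), with 6 falls and 1 rise adjusted over the list alone. The median was -0.15 (camera adjusted p = 0.00161, and adjusted p = 0.715 with an estimated correlation). No gene of 47 large subunit proteins passed in edgeR, adjusted over the list alone or over all genes. The list median was -0.12 (camera adjusted p = 0.0345, and adjusted p = 0.757 with an estimated correlation). Among 25 genes of glycolysis and hypoxia Adm (-0.82, SE 0.07) and the glucose transporter gene Slc2a1 (-0.46, SE 0.06) fell, and 3 fell and 1 rose adjusted over the list alone. The list's median was -0.12 (camera adjusted p = 0.0435, and adjusted p = 0.524 with an estimated correlation).

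Of the other lists in footprints, 3 were higher as sets, with no member past the test over all genes. Initiation factors (45 measured) had a median of 0.11 (camera adjusted p = 0.0112, and adjusted p = 0.573 with an estimated correlation). DNA replication genes (44) had a median of 0.11 (camera adjusted p = 0.0138, and adjusted p = 0.557 with an estimated correlation), and proteasome genes (37) of 0.10 (camera adjusted p = 0.0190, and adjusted p = 0.582 with an estimated correlation). Adjusted over the list alone 2 replication genes rose and 1 fell, and no member of the other sets passed. The smallest unadjusted p-values were for Eif3f (0.26, SE 0.06, adjusted p = 0.0885), Ccne1 (0.37, SE 0.06, adjusted p = 0.0517) and Pomp (0.31, SE 0.07, adjusted p = 0.0886). The 4 measured blood cell markers were lower as a set (median -1.004, camera adjusted p = 0.0345, adjusted p = 0.524 with an estimated correlation); the macrophage gene Cd68, also expressed by melanoma cells, fell (-0.89, SE 0.12). Among 38 genes of rRNA modification 1 rose and none fell, also adjusted over the list alone: Nop58 (0.41, SE 0.05; list median 0.09, camera adjusted p = 0.0691). Among 31 genes of the ATF4 response 2 fell, also adjusted over the list alone: Ddit4 (-0.83, SE 0.12) and Pck2 (-0.54, SE 0.07; list median -0.06, camera adjusted p = 0.298). Among 24 genes of cholesterol synthesis 1 fell and none rose, and 1 rose and 4 fell adjusted over the list alone (median -0.02, camera adjusted p = 0.160). The 6 remaining lists of translation, division and respiration had no member past the test, over all genes or adjusted over the list alone. Their medians and camera adjusted p were 0.12 and 0.0691 for elongation factors (16 genes), 0.07 and 0.0819 for mitosis genes (36), and 0.01 and 0.743 for histones (36, mean -0.01). They were -0.01 and 0.823 for nuclear oxidative phosphorylation (73, test pointing up), 0.02 and 0.613 for mitochondrially encoded genes (13), and 0.00 and 0.677 for decay factors (18). Some of these medians change sign with the scaling: histones -0.03, mitochondrially encoded genes -0.02 and decay factors -0.04 with the size factors of DESeq2, and oxidative phosphorylation 0.01 and cholesterol synthesis 0.00 with upper-quartile scaling. Of 16 ligand genes none passed over all genes, and 4 rose and 6 fell adjusted over the list alone (median -0.17, camera adjusted p = 0.335), with Cd274 at -1.04, SE 0.15, adjusted p = 0.0506. Of 6 fibroblast and endothelial markers Postn alone fell, and 2 rose and 2 fell adjusted over the list alone; the median was 0.34 while camera pointed down (adjusted p = 0.633). Fry called no list in footprints, its smallest adjusted p being 0.0755.

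Of 13779 genes tested in both assays, 38 rose and 121 fell in both, where independent lists of these sizes would share 9.81 and 27.0, and 9 had opposite calls. Enpp2 rose in both assays, and Postn, Col4a2, Tap2, Tap1, H2-K1, Kit, Oca2, Atf6, Eda2r, Ephx1 and Adm fell in both. Ddx58 fell in input RNA (16.2 and 15.3 CPM in SCR, 7.85 and 8.97 in KO cells) and rose in footprints (17.3 and 16.1 against 28.4 and 31.6 CPM), and Rps29 rose in input RNA and fell in footprints. Across genes, which are not independent replicates, the fold changes of the assays correlated with a Pearson r of 0.177 and a Spearman rho of 0.156.

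**Figure D1:**
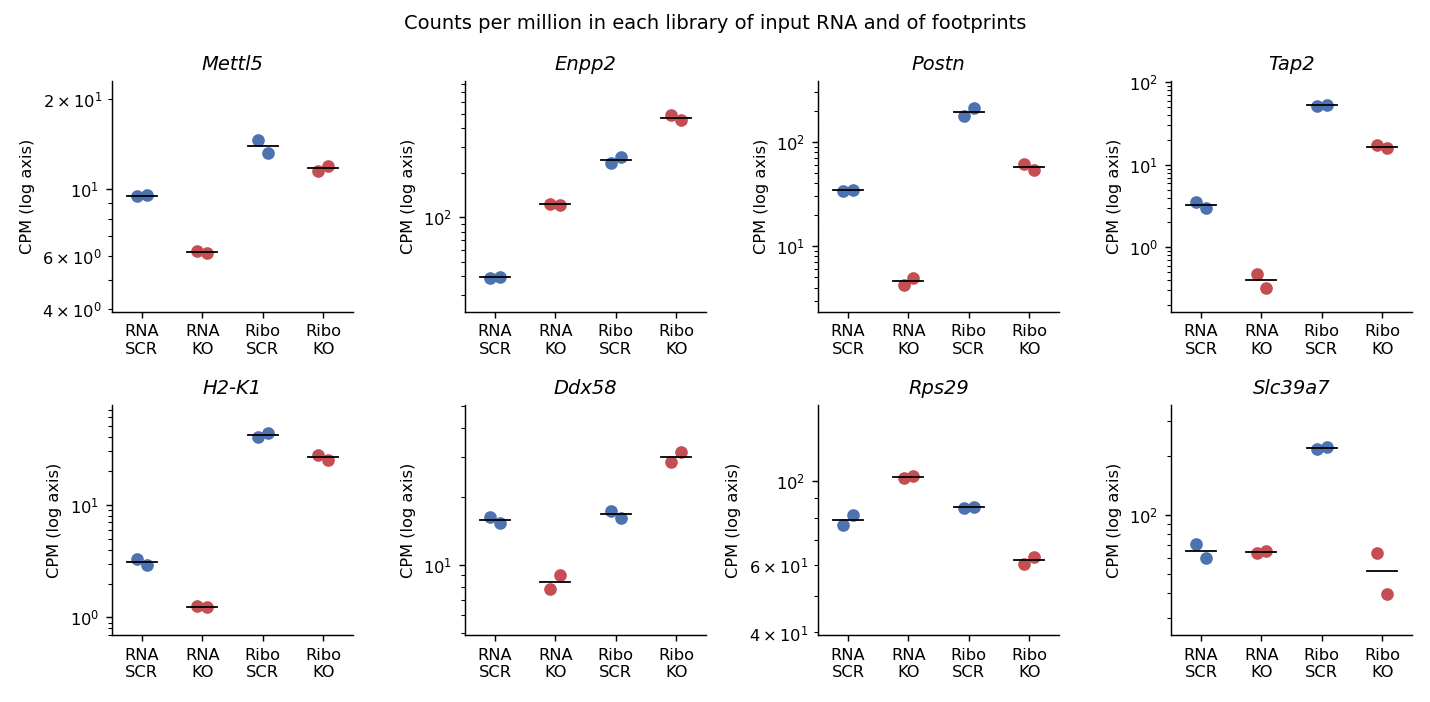
CPM of 8 genes in each library of cultured cells, on a log axis: points are libraries, lines the mean of the 2 libraries of a genotype, with input RNA and footprints side by side. Ddx58 was lower in KO input RNA and higher in KO footprints, while Postn and Tap2 were lower in both.

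Translational efficiency (TE), the footprint level relative to the input RNA, showed which mRNAs carried more or fewer ribosomes for their amount. It was tested as the interaction of genotype and assay over all 8 libraries. Of 23211 genes tested, 183 rose and 790 fell in KO cells, 81.2% of the calls being falls; with upper-quartile scaling 58.2% of 698 calls were falls. The largest rises were in Cntn1, a cell adhesion gene (log2 fold change 1.92, SE 0.18, adjusted p = 0.0143), the complement protease gene C1s1 (1.63, SE 0.23, adjusted p = 0.0208), Ddx58 (1.54, SE 0.14, adjusted p = 0.0143) and the receptor kinase gene Axl (1.25, SE 0.10, adjusted p = 0.0140). After them came Adm (1.17), S100a11 (1.14), Tap2 (1.13), Cp (1.09), Map2 (1.09) and the interferon-induced gene Ifi27 (1.07). The largest falls included Dicer1 (-2.49, SE 0.45, adjusted p = 0.0330), Slc39a7 (-2.29, SE 0.25, adjusted p = 0.0205), Cubn (-1.67, SE 0.14, adjusted p = 0.0140) and the metallothionein gene Mt2 (-1.46, SE 0.27, adjusted p = 0.0351). The other large falls were in genes of small structured RNAs that are not translated and exist in many copies: ENSMUSG00002076377 (-3.75), U3 (-3.11), Rn7s6 (-1.94), 2 genes named Metazoa_SRP (-1.78 and -1.72) and ENSMUSG00002075045 (-1.55). Dicer1 footprints differed between SCR replicates, at 4551 and 2181 CPM against 510 and 755 CPM in KO cells. Slc39a7 had 70.8 and 60.4 CPM of input RNA in SCR and 64.0 and 65.5 in KO cells, and 216 and 223 against 63.9 and 39.8 CPM of footprints. In place of the 973 calls of the full data, edgeR called 3 genes without input RNA SCR replicate 1. It called 0 without input RNA SCR replicate 2 (3804 at an unadjusted p below 0.05) and 0 without input RNA KO replicate 1 (3645 at an unadjusted p below 0.05). In the full data limma's voom called 581 and DESeq2 1722.

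Ribosomal protein mRNAs had lower TE in KO cells: 16 of 34 small subunit and 21 of 48 large subunit genes fell and none rose, and 31 and 39 fell adjusted over the list alone. Their medians were -0.59 and -0.48 (camera adjusted p = 5.87e-23 and 1.13e-21, and adjusted p = 0.238 and 0.235 with an estimated correlation). With upper-quartile scaling the medians were -0.49 and -0.39 and 8 and 12 genes fell. Rps29 (-1.05, SE 0.09, adjusted p = 0.0140), Rps21 (-1.07, SE 0.14, adjusted p = 0.0205), Rpl13 (-0.79, SE 0.10, adjusted p = 0.0205) and Rpl27a (-0.82, SE 0.12, adjusted p = 0.0212) were among those that fell. Interferon-stimulated genes had higher TE: of 38 genes 3 rose and none fell, 17 adjusted over the list alone, with Ddx58 and Ifih1, another RNA sensor gene (0.90, SE 0.18), among those that rose. The members' median was 0.63 (camera adjusted p = 3.75e-13, and adjusted p = 0.0716 with an estimated correlation). Of 31 ATF4 response genes 6 fell and none rose, 19 adjusted over the list alone, with Slc7a1 (-0.83, SE 0.13), Slc7a11 (-0.72, SE 0.11), Slc7a5 (-0.68, SE 0.09) and Atf4 (-0.63, SE 0.09). The median over members was -0.31 (camera adjusted p = 4.74e-08, and adjusted p = 0.231 with an estimated correlation). Of 40 histone genes 9 fell, 16 adjusted over the list alone, for example H2bc4 (-0.82, SE 0.12). The median was -0.56 (camera adjusted p = 5.71e-10, and adjusted p = 0.231 with an estimated correlation). Of 73 nuclear oxidative phosphorylation genes 4 fell, 35 adjusted over the list alone, with Uqcr11 at -0.77, SE 0.13. The list median was -0.34 (camera adjusted p = 4.62e-11, and adjusted p = 0.431 with an estimated correlation). Of 37 proteasome genes 4 fell, 8 adjusted over the list alone, with Psmb6 at -0.61, SE 0.13. The list's median was -0.20 (camera adjusted p = 9.64e-06, and adjusted p = 0.431 with an estimated correlation). Of 38 rRNA modification genes 5 fell, 12 adjusted over the list alone, among them the rRNA methyltransferase genes Emg1 (-0.72, SE 0.13) and Bud23 (-0.69, SE 0.11). The list median was -0.19 (camera adjusted p = 0.000203, and adjusted p = 0.431 with an estimated correlation). None of these lists had a member that rose except the interferon-stimulated genes.

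Of 23 p53 targets 7 fell and 1 rose in TE, and 11 and 1 adjusted over the list alone (median -0.26, camera adjusted p = 0.00253, and adjusted p = 0.249 with an estimated correlation). Cdkn1a (-0.64, SE 0.09), the p53 regulator gene Mdm2 (-0.54, SE 0.08) and Phlda3 (-1.11, SE 0.17) fell. Of 24 genes of the unfolded protein response 3 fell, 8 adjusted over the list alone, with Syvn1 at -0.54, SE 0.09 (median -0.23, camera adjusted p = 0.00272, and adjusted p = 0.440 with an estimated correlation). Of 44 replication genes 5 fell, 6 adjusted over the list alone, with E2f1 at -0.71, SE 0.11 (median -0.14, camera adjusted p = 0.00365, and adjusted p = 0.431 with an estimated correlation). Of 45 initiation factors Eif6 (-0.76, SE 0.13) and Eif2b4 (-0.57, SE 0.11) fell, 8 adjusted over the list alone (median -0.12, camera adjusted p = 0.00580, and adjusted p = 0.477 with an estimated correlation). Of 18 decay factors Upf1 (-0.54, SE 0.07) and Rbm8a (-0.56, SE 0.11) fell, 5 adjusted over the list alone. The members' median was -0.20 (camera adjusted p = 0.00948, and adjusted p = 0.231 with an estimated correlation). Of 22 melanocyte genes the melanosome genes Pmel (-0.81, SE 0.15) and Mlana (-0.75, SE 0.12) and Kit (-0.63, SE 0.13) fell, and 7 fell and 2 rose adjusted over the list alone. The median over members was -0.23 (camera adjusted p = 0.0187, and adjusted p = 0.431 with an estimated correlation). Of 16 elongation factors none passed over all genes and 2 fell adjusted over the list alone (median -0.17, camera adjusted p = 0.0438, 0.0727 with RLE scaling, and adjusted p = 0.44 with an estimated correlation). The 13 mitochondrially encoded genes were higher as a set with no member past the test. The median was 0.30 (camera adjusted p = 0.0147, and adjusted p = 0.562 with an estimated correlation). The other lists had no set call in TE. Of 17 MHC class I genes Tap2 alone rose, 3 adjusted over the list alone (median 0.04, camera adjusted p = 0.0690). Of 26 genes of glycolysis and hypoxia Adm rose and Slc2a1 fell (-0.53, SE 0.07), and 2 rose and 1 fell adjusted over the list alone (median 0.02, mean -0.26, camera adjusted p = 0.183). Of 24 cholesterol genes Idi1 rose (0.47, SE 0.10) and Srebf2 fell (-0.39, SE 0.08), and 3 rose and 5 fell adjusted over the list alone (median 0.04, mean -0.01, camera adjusted p = 0.597). Of 8 fibroblast markers Postn rose (0.92, SE 0.16), 2 adjusted over the list alone (median 0.16, -0.08 with the size factors of DESeq2, camera adjusted p = 0.0794). None passed among 36 mitosis genes (median -0.00, 0.09 with upper-quartile scaling, camera adjusted p = 0.302), 18 ligand genes (-0.07 with the test pointing up, 0.02 with upper-quartile scaling, 0.597) and 6 blood markers (-0.13, 0.801). By fry 9 lists passed in TE, with an adjusted p of 0.00955 for interferon-stimulated genes, the ATF4 response and decay factors, and of 0.00997 for p53 targets. The others were histones and the large subunit (0.0213), the small subunit (0.0228), and rRNA modification and DNA replication (0.0256).

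TE contains the input RNA value, and so shares libraries with that comparison: the fold changes of input RNA and TE had a Pearson r of -0.34 across 19520 genes, and 546 genes had opposite calls. Each of the 10 largest TE rises had less input RNA in KO cells, and ribosomal protein genes rose in input RNA. In the authors' deposited table of TE, 16872 genes had an adjusted p, of which 366 rose and 1467 fell (80.0% falls). Of the 962 genes called here that are also in the authors' deposited table, 951 were called there, all in the same direction, and the fold changes correlated with a Pearson r of 0.944 across 16388 genes. Of 34 small and 48 large ribosomal subunit genes 24 and 25 fell in the authors' deposited table, and 11 of 36 interferon-stimulated genes rose.

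**Figure D2:**
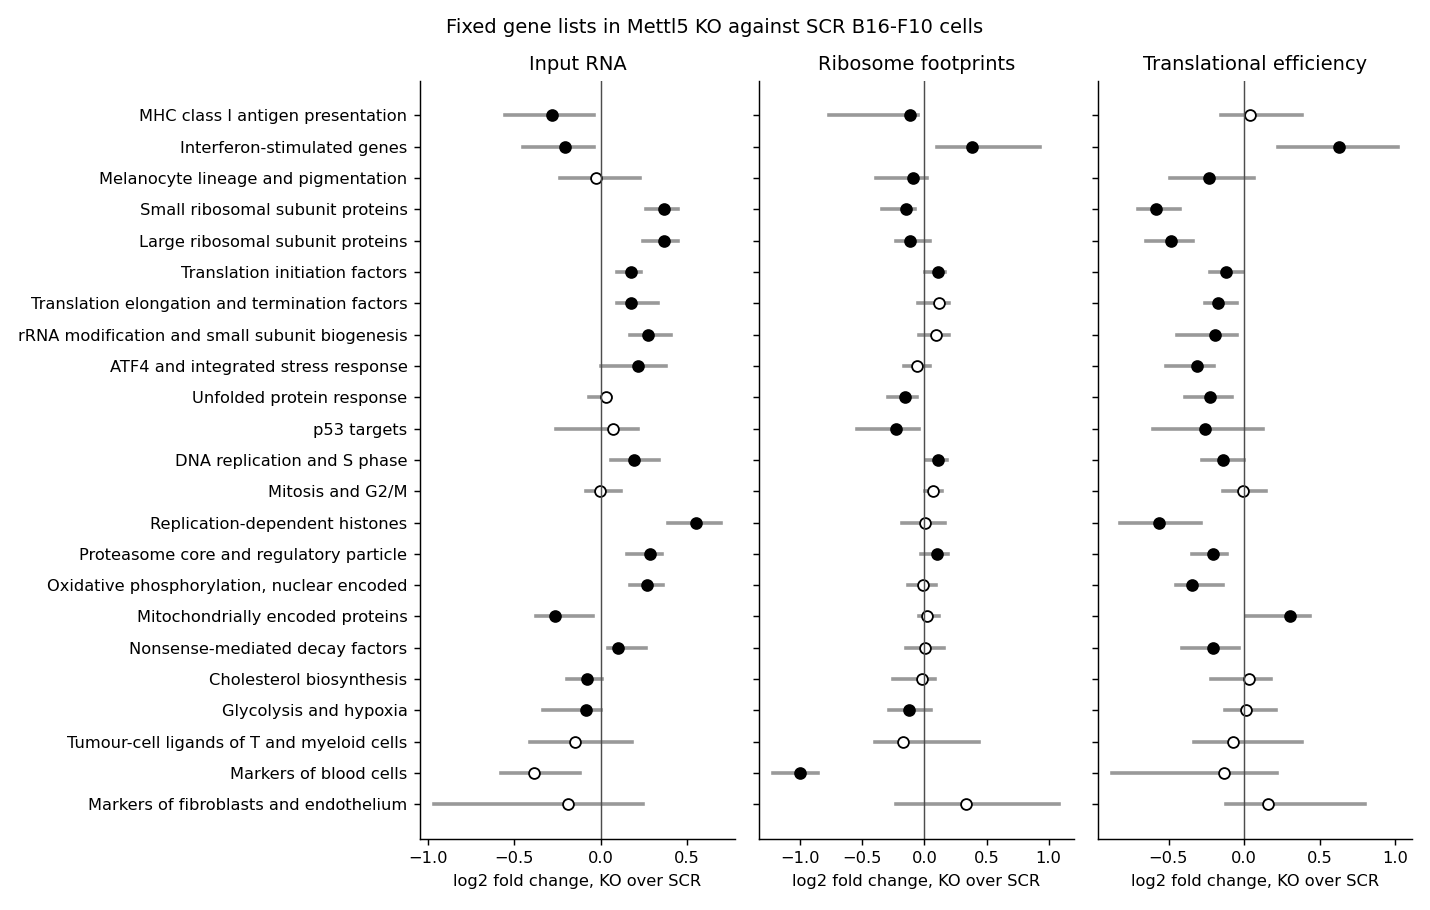
Median log2 fold change (KO minus SCR) of the measured members of each of the 23 gene lists, in input RNA, footprints and TE, where bars span the quartiles of the members and filled points mark lists with a camera adjusted p below 0.05. Ribosomal protein genes were higher in input RNA (median 0.37 for each subunit) and lower in TE (-0.59 and -0.48), and interferon-stimulated genes were lower in input RNA (-0.21) and higher in TE (0.63).

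The study was concerned with peptides that tumour cells translate outside annotated coding sequences, and the authors listed such open reading frames (nuORFs) whose abundance they found larger in KO or in SCR cells. The KO list held 1383 nuORFs on 1253 genes and the SCR list 1614 on 1443 genes, with none in both lists. In the KO list 667 (48.2%) were in transcripts without an annotated coding sequence and 388 (28.1%) upstream of one, and in the SCR list 283 (17.5%) and 841 (52.1%). Upstream ORFs that overlap the coding sequence numbered 120 in the KO and 267 in the SCR list, downstream ORFs 132 and 157, internal ORFs 63 and 54, and overlapping downstream ORFs 13 and 12. In pseudogenes lay 550 (39.8%) of the KO and 201 (12.5%) of the SCR nuORFs, and footprints on processed pseudogenes cannot be told from those on the parent genes; without them upstream ORFs made up 46.6% and 59.5%. Translation started at ATG in 71.1% of the KO and 52.0% of the SCR nuORFs, and otherwise at CTG (222 and 467), GTG (125 and 200) or ACG (53 and 107). KO and SCR nuORFs had medians of 34 and 44 P-sites in frame. The lists were chosen by direction, so no test of direction was made on them.

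P-sites and RPKM in these lists were read as totals over all libraries, because the same scale factor links them in both lists. The sources used here do not state this, so none of them is taken as a level per genotype. The nuORFs with the highest RPKM were named, a choice made after the values were seen, at coordinates of GRCm39 that span any introns. In the KO list these were upstream ORFs with ATG starts in Sirt2, a deacetylase gene (chromosome 7, 28466277 to 28471255, 33 nt, 654 P-sites, 231 RPKM), in Zfp322a (chromosome 13, 23552319 to 23552354, 192 RPKM) and in the centromere gene Cenpq (chromosome 17, 41244077 to 41244103, 169 RPKM). They were followed by an upstream ORF from CTG in the metallothionein gene Mt1 (chromosome 8, 94905853 to 94905915, 131 RPKM) and an internal ORF from ACG in Eif1b (chromosome 9, 120323296 to 120323322, 127 RPKM). In the SCR list these were upstream ORFs in Hnrnpab, an RNA-binding protein gene (GTG, chromosome 11, 51497559 to 51497594, 7810 P-sites, 2759 RPKM), Nop10 (ACG, chromosome 2, 112092325 to 112092360, 555 RPKM) and the histone variant gene H2az1 (ACG, chromosome 3, 137570370 to 137570399, 299.7 RPKM). Upstream ORFs that overlap the coding sequence were listed in Gpnmb, a melanosome glycoprotein gene (ATG, chromosome 6, 49013601 to 49019745, 168 nt, 1228 RPKM), and Cycs, which encodes cytochrome c (GTG, chromosome 6, 50542633 to 50543418, 279 RPKM). The Gpnmb ORF had 17690 P-sites in its own frame and 19925 in another frame. Among the 37 ATF4 response genes, 3 hosted KO nuORFs (Asns, Ppp1r15a, Slc7a11) and 5 hosted SCR nuORFs (Chac1, Psph, Pycr1, Slc7a5, Trib3). Among the 19 MHC class I genes, none hosted KO nuORFs and 1 hosted SCR nuORFs (Canx).

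**Figure D3:**
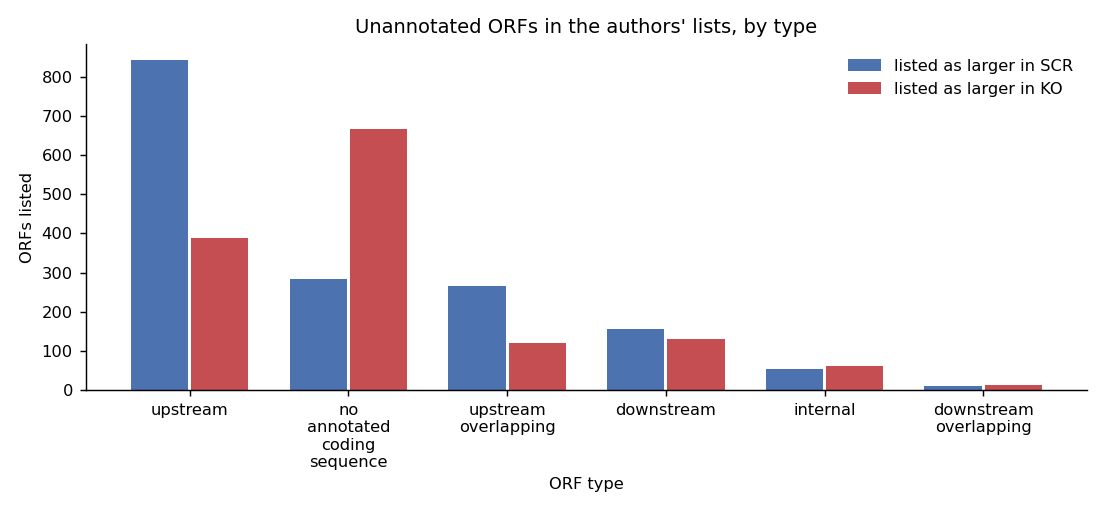
Number of nuORFs by position relative to the annotated coding sequence, for the authors' list larger in KO (1383 nuORFs) and the list larger in SCR cells (1614 nuORFs). In the KO list 667 were in transcripts without an annotated coding sequence and 388 upstream, and in the SCR list 283 and 841.

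TCRβ sequencing of blood addressed whether the T-cell repertoire differed between mice that carried KO (n = 5) and SCR tumours (n = 4). Mice with KO tumours had more TCRβ clonotypes, with fewer reads in the largest ones. Thinned to equal reads, they had 52127 ± 6221 clonotypes (SD) against 39342 ± 4916 in mice with SCR tumours (ratio 1.32, exact permutation p = 0.0159). Shannon entropy was 8.06 ± 0.279 against 7.21 ± 0.471 nats (exact permutation p = 0.00794), and clonality 0.257 ± 0.0179 against 0.318 ± 0.0365 (exact permutation p = 0.00794). The inverse Simpson index was 2249.9 ± 763 against 1042 ± 428 (exact permutation p = 0.0159). The 100 largest clonotypes held 9.67 ± 2.16% of the reads in KO and 19.6 ± 7.75% in SCR mice (exact permutation p = 0.00794). All 5 KO mice lay beyond all 4 SCR mice in each of these measures and in CDR3 length. The smallest two-sided p that an exact test of 4 against 5 mice allows is 0.00794, and Benjamini-Hochberg adjusted values over the 7 measures were 0.0111 to 0.0159. The difference in clonotypes was 10578 without SCR replicate 2 (exact permutation p = 0.0536), and the inverse Simpson index had an exact permutation p of 0.0536 without any 1 of the SCR mice. Without SCR replicate 2 the difference in the top 100 share was -6.39 percentage points (exact permutation p = 0.0179) in place of -9.94. The share of the 10 largest clonotypes was not told apart (difference -1.12 percentage points, exact permutation p = 0.0873).

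The CDR3, the loop that contacts the antigen, was on average 13.95 ± 0.0432 amino acids long over clonotypes in KO and 13.80 ± 0.0925 in SCR mice (difference 0.148, exact permutation p = 0.00794). Weighted by reads the difference was 0.0465 (exact permutation p = 0.238). Clonotypes of 10 to 15 amino acids, a range that was not planned, made up 91.9 ± 0.213% in KO and 92.8 ± 0.499% in SCR mice (exact permutation p = 0.00794), but none of 8 single lengths passed (smallest at 16 amino acids, exact permutation p = 0.0159, adjusted p = 0.127). Pairs of KO mice shared fewer amino acid CDR3s than pairs of SCR mice, with a mean Jaccard overlap of 21.3% over 10 pairs against 25.02% over 6 pairs (difference -3.76, exact permutation p = 0.00794). The overlap depends on repertoire size. With equal numbers of CDR3s per mouse the difference was -6.83 (exact permutation p = 0.00794). That setting keeps a smaller part of the larger KO repertoires, which by itself lowers their overlap. Lower sharing was therefore not told apart from the larger repertoires of KO mice. No V or J gene passed by share of reads among 23 tested (exact permutation tests, 3 at an unadjusted p below 0.05; limma 0 with 4 at an unadjusted p below 0.05). The smallest p-values were for TRBV12-2 (8.59% in KO, 9.71% in SCR mice, exact permutation p = 0.0159, adjusted p = 0.274) and TRBJ2-3 (0.487 and 0.626%, exact permutation p = 0.0238, adjusted p = 0.274). Next were TRBV26 (5.78 and 5.10%, exact permutation p = 0.0397, adjusted p = 0.292) and TRBV4 (13.3 and 12.5%, exact permutation p = 0.0556, adjusted p = 0.292). By share of clonotypes 11 of 21 genes passed, among them TRBV4 (17.0 ± 0.419% in KO, 15.7 ± 0.947% in SCR mice) and TRBJ2-7 (42.1 ± 0.797 and 44.3 ± 1.54%), each with an exact permutation p of 0.00794 (adjusted p = 0.0208). The largest clonotype of each mouse used TRBV12-2 and TRBJ2-2 in SCR mouse 1 (0.339% of reads), TRBV14 and TRBJ2-2 in SCR mice 2 and 4 (0.446 and 0.2002%), and TRBV16 and TRBJ2-2 in SCR mouse 3 (0.249%). In KO mice it used TRBV4 and TRBJ2-7 (mouse 1, 0.135%), TRBV12-1 and TRBJ2-7 (mouse 2, 1.31%), TRBV16 and TRBJ1-2 (mouse 3, 0.238%), TRBV4 and TRBJ1-2 (mouse 4, 0.176%), and TRBV12-2 and TRBJ2-2 (mouse 5, 0.129%).

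**Figure D4:**
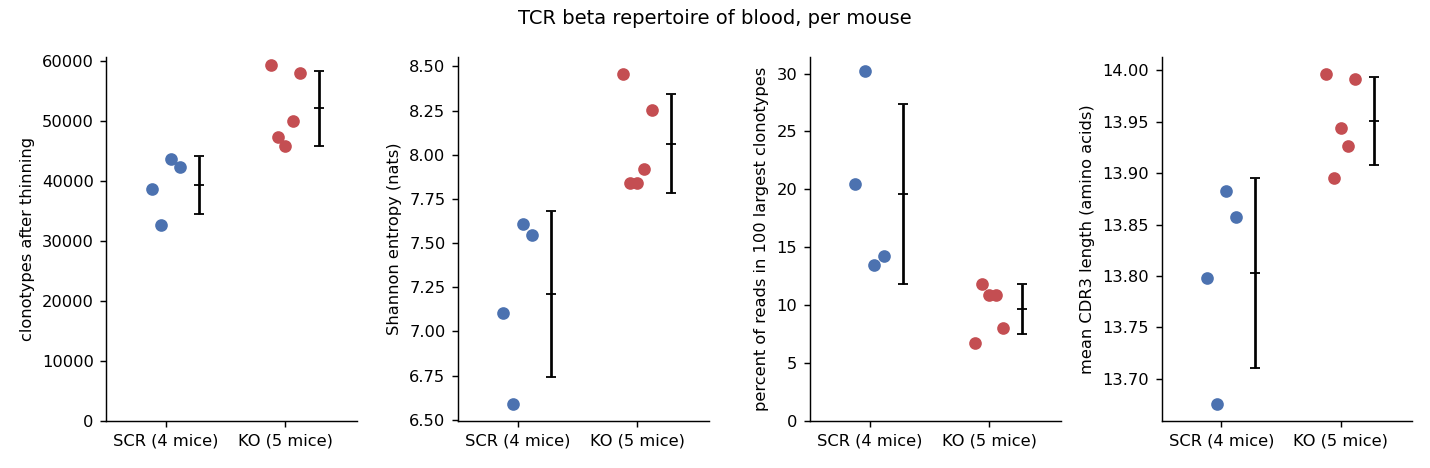
Clonotypes after thinning to equal reads, Shannon entropy (nats), percent of reads in the 100 largest clonotypes and mean CDR3 length (amino acids) in each of 4 SCR and 5 KO mice, with points for mice and bars for the mean ± SD. Every KO mouse lay above every SCR mouse in clonotypes, entropy and CDR3 length and below it in the share of the 100 largest clonotypes (9.67 ± 2.16% against 19.6 ± 7.75%).

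Single-cell sequencing of CD45-positive tumour cells had 1 library per genotype, so no test between genotypes was made and each difference is between these 2 libraries; intervals cover counting error only. Of 8239 SCR and 8360 KO cells, macrophage-like cells made up 51.8% (95% binomial interval 50.7 to 52.9) and 49.98% (48.9 to 51.1), their largest clusters being 0 in SCR and 1 in KO. Monocyte-like cells made up 15.1% (14.3 to 15.9) of SCR and 19.6% (18.7 to 20.4) of KO cells, and melanoma-like cells, which the CD45 sort should remove, 2.21% (1.90 to 2.55) and 2.99% (2.64 to 3.38). T-like cells numbered 192 and 200 (2.33%, 2.02 to 2.68, and 2.39%, 2.08 to 2.74). NK-like cells made up 1.53% and 1.28%, dendritic cells of the cDC2 type 3.87% and 4.27% and mature migratory dendritic cells 1.77% and 2.08%, with overlapping intervals. Neutrophil-like (63 and 44), plasmacytoid dendritic (40 and 38) and fibroblast-like cells (29 and 37) were few. Cluster 2, where T-cell genes were mixed with macrophage genes at a median of 11986 UMIs against 3248 in T-like cells, was left unnamed. It held 5.53% (5.05 to 6.05) of SCR and 7.34% (6.79 to 7.92) of KO cells. Cluster 8, of phagocytes, held 9.71% of SCR and 3.35% of KO cells, a cluster mostly of 1 library, and a mixed cluster with plasma cell genes 1.41% and 2.26%. The doublet caller marked 1 cell of 16795 and so did not work, which leaves doublets in these shares. A sum of macrophage-like, monocyte-like and unnamed phagocyte clusters, defined after the clusters were seen, made up 79.7% (78.9 to 80.6) of SCR and 76.0% (75.03 to 76.9) of KO cells. From the SCR to the KO library Mettl5 went from 31.1 CPM (95% interval 26.9 to 35.7) to 21.9 CPM (18.7 to 25.6) in melanoma-like cells, and from 12.9 to 13.8 CPM in phagocytes.

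**Figure D5:**
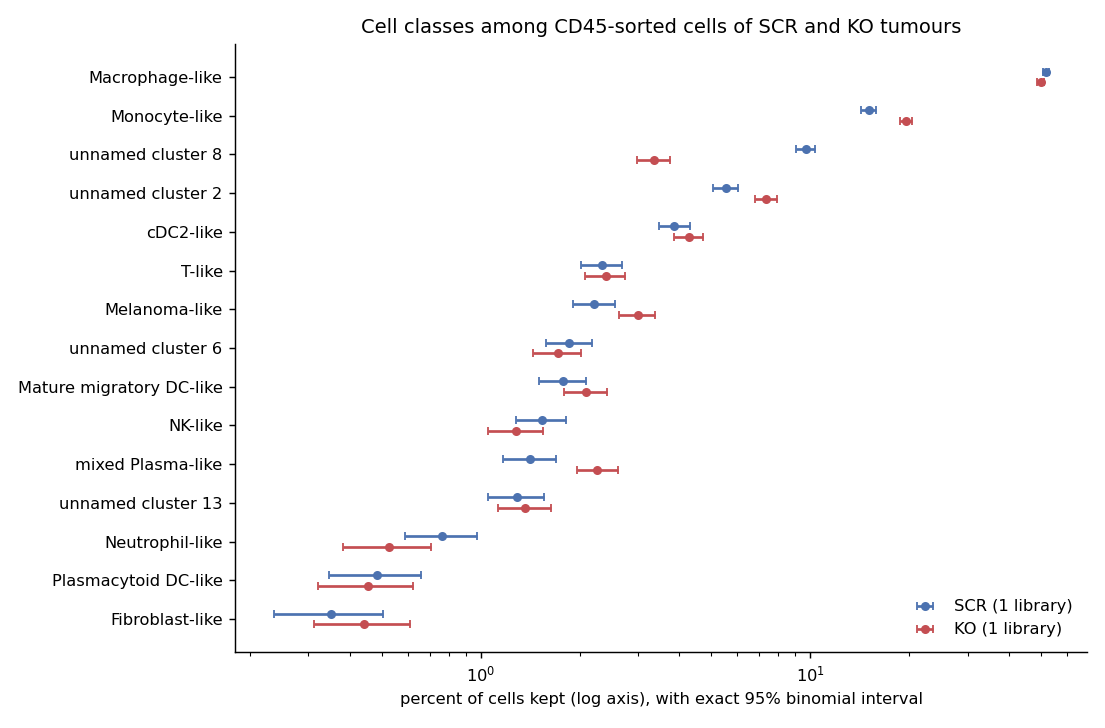
Percent of cells in each class or cluster in the SCR (8239 cells) and KO library (8360 cells), on a log axis, where bars are exact 95% binomial intervals, which cover counting error only, with 1 library per genotype. Monocyte-like cells were at 15.1 and 19.6%, and cluster 8 at 9.71 and 3.35%.

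In T-like cells, transcripts of cytotoxic effectors were higher and those of regulatory T cells lower in the KO library. This class is 1 cluster, with Ctla4, Il17a and the γδ receptor gene Trdv4 among its leading genes. A different mix of T-cell kinds therefore cannot be told apart from changed expression within cells. Gzma is also the leading gene of the NK-like cluster, so misplaced NK cells are not excluded as its source. Gzma, a granzyme, went from 22.8 CPM (95% interval 14.6 to 33.9) to 172 CPM (147 to 200.3), the pore-forming protein gene Prf1 from 51.3 to 154, Serpinb9 from 57.9 to 165 and Gzmk from 29.4 to 78.5 CPM. Of 17 cytotoxic genes 11 were higher (median log2 ratio 0.35, at the 100 percentile of 10000 random lists matched on expression). Of 13 inhibitory receptor and exhaustion genes 10 were higher (median 0.42, percentile 100), such as Lag3 (47.5 to 83.6 CPM), Rgs16 (117 to 216), Nr4a2 (206 to 355) and Entpd1 (38.0 to 65.2). Of 13 regulatory T-cell genes 11 were lower (median -0.33, percentile 0): the lineage factor gene Foxp3 went from 232 CPM (95% interval 204 to 263) to 124 CPM (103 to 148), Il2ra from 255 to 151, Izumo1r from 116 to 75.4 and Il10 from 89.3 to 35.7 CPM. Il17a, a cytokine of γδ and helper T cells, went from 291 to 119 CPM. Proliferation genes (16 of 18 lower, median -0.17, percentile 0.59), such as Rrm2 (106 to 55.0 CPM), and MHC class II genes (5 of 6 lower, median -0.50, percentile 0.01), such as Cd74 (1739 to 1205), were lower. Interferon-stimulated genes (17 of 27 lower, median -0.11, percentile 2.27), such as Cxcl10 (1656 to 710.5), were lower. Genes of the interferon-gamma response (12 of 19 lower, median -0.21, percentile 0.06) and inflammatory cytokines (8 of 9 lower, median -0.21, percentile 0.61) were lower as well, the latter at -0.11 when the 8% highest doublet scores were left out (percentile 9.11). Naive and memory genes (median 0.05, percentile 69.1), MHC class I (-0.03, 23.8), tumour-associated macrophage genes (-0.00, 45.1) and dissociation stress (0.01, 59.0) were not apart from random lists. Thbs1, a gene of monocytes and platelets, went from 59.8 to 229 CPM in T-like cells, and Gzma from 0.509 to 2.67 CPM in phagocytes, which do not express it. In unnamed cluster 2, which also has T-cell genes such as Cd3d among its markers (456 and 614 cells), cytotoxic genes (8 of 20 higher, median -0.03, percentile 10.2) and regulatory T-cell genes (8 of 14 higher, median 0.01, percentile 47.1) were not apart from random lists. Inhibitory receptor and exhaustion genes were higher there (12 of 16, median 0.20, percentile 100). The T-like class could not be compared at resolutions 0.5 and 1.5 or on clustering anew with the 1 marked cell kept. With up to 20% mitochondrial UMIs it held 63 and 47 cells, under 100.

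In NK-like cells of the KO library the chemokine gene Xcl1 was lower (1863 CPM (95% interval 1736 to 1997) to 575 CPM (498 to 660.0)), as were the granzyme gene Gzmc (791 to 435 CPM), Ccl4 (7218 to 4493) and Myc (678 to 232). Of 16 cytotoxic genes 9 were lower (median -0.17, percentile 0.5), and of 9 interferon-stimulated genes 7 (median -0.61, percentile 0.01), with Isg15 (746 to 295 CPM), Ifit1 (256 to 125.8) and Cxcl10 (1237 to 426). Genes of dissociation stress were lower (17 of 18, median -0.35, percentile 0), and the 8 measured macrophage genes were higher (median 0.67, percentile 100), along with the myeloid gene Lyz2 (86.8 to 935 CPM).

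In the sum of phagocytes of the KO library, genes of tolerogenic tumour-associated macrophages and inflammatory cytokines were lower and interferon-stimulated genes slightly higher. Of 26 tumour-associated macrophage genes 21 were lower (median -0.17, percentile 0): Spp1, which encodes osteopontin, went from 1152 CPM (95% interval 1144 to 1160) to 534 CPM (528 to 540.0), the arginase gene Arg1 from 210.3 to 119 and the heme oxygenase gene Hmox1 from 1260 to 761 CPM. Of 18 inflammatory cytokine genes 15 were lower (median -0.32, percentile 0). Ifnb1, which encodes interferon beta, went from 116 to 43.2 and Cxcl3 from 102 to 38.6 CPM. Spp1, Arg1 and Cxcl3 are leading genes of cluster 8, part of this sum (800 SCR and 280 KO cells). For these genes its smaller share cannot be told apart from lower expression within cells. In macrophage-like cells, without cluster 8, the medians of the tumour-associated macrophage and cytokine lists were -0.18 and -0.15 (percentile 0 each). Their clusters also differed in size, such as 1 (764 SCR, 938 KO cells) and 12 (522, 429), so a changed mix is not excluded. Dissociation stress genes were higher in this class (18 of 20, median 0.19, percentile 100). Of 39 interferon-stimulated genes 31 were higher (median 0.13, percentile 100), such as Ifi44 (4.35 to 6.63 CPM), though Ifih1 (225 to 162) and Cxcl10 (1073 to 803) were lower. Of 29 genes of the interferon-gamma response 22 were higher (median 0.10, percentile 99.8), such as Gbp8 (18.05 to 22.8). These lists did not move alike in all parts of the sum. Tumour-associated macrophage genes were lower in cluster 6 (16 of 19, median -0.26, percentile 0.01), but not apart from random lists in monocyte-like cells (13 of 24 higher, median 0.04, percentile 90.1) or in unnamed clusters 8 (-0.03, 30.9) and 13 (-0.07, 22.5). Inflammatory cytokines were lower in monocyte-like cells (median -0.09, percentile 0.515) and clusters 8 (-0.19, 0.02) and 13 (-0.61, 0), but not apart in cluster 6 (-0.16, 4.44). Interferon-stimulated genes were lower in clusters 6 and 13 (13 of 15 in each, medians -0.26 and -0.30, percentiles 0.305 and 0.385). Interferon-gamma response genes were lower in monocyte-like cells (18 of 26, median -0.09, percentile 0) and in cluster 6 (5 of 8, median -0.28, percentile 1.66). MHC class I genes had a median of 0.07 (percentile 94.0), with H2-Q7 from 84.0 to 106 CPM, MHC class II genes -0.02 (18.9), proliferation 0.06 (75.9), stress 0.07 (95.7) and melanoma transcripts -0.01 (23.5). Within parts of the sum, MHC class I genes were higher in macrophage-like cells (0.08, percentile 98.1) and lower in cluster 6 (-0.24, 1.71), and MHC class II genes were lower in cluster 8 (all 6, median -0.33, percentile 0.01) and in monocyte-like cells. Cytotoxic genes were at 0.16 (percentile 99.7, but 0.05 when the 1 marked cell was kept and all cells were clustered anew), inhibitory receptors at 0.04 (49.2), naive and memory genes at 0.05 (61.1) and regulatory T-cell genes at -0.11 (5.09), all T-cell lists that phagocytes should lack. Cytotoxic genes were lower in clusters 8 (-0.48, 0.01) and 13 (-0.54, 0.23), and regulatory T-cell genes in cluster 8 (-0.69, 0). The largest ratios were in immunoglobulin genes, Ighg2b from 0 (upper limit 0.0508) to 4.58 CPM, Igkc from 0.0688 to 2.59 and Jchain from 0.0826 to 2.72 CPM, and in Nts (0.151 to 1.62) and the mast cell protease gene Cma1 (0.303 to 1.64). Jchain turned to a log2 ratio of -1.17 with up to 20% mitochondrial UMIs. The smallest were in Ifna5 (1.87 to 0.0810 CPM), Ccl17 (2.06 to 0.0972) and Ifna1 (2.84 to 0.178).

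In monocyte-like cells all 8 measured MHC class II genes were lower in the KO library (median -0.37, percentile 0), with H2-Eb1 from 2878 CPM (95% interval 2842 to 2914) to 2217 CPM (2187 to 2247), H2-DMa from 476 to 347 and H2-DMb1 from 567 to 423 CPM. Dissociation stress genes were lower too (16 of 20, median -0.13, percentile 0). Of markers of other cell types, the 5 measured cytotoxic genes were lower (median -0.33, percentile 0.01) and melanoma transcripts higher (3 of 5, median 0.36, percentile 99.79). Interferon-stimulated genes were higher (28 of 39, median 0.13, percentile 100), such as Oas2 (26.0 to 36.5 CPM). Ifnb1 (13.3 to 3.23), the chemokine genes Ccl3 (401 to 233) and Ccl4 (2614 to 1574) and the lectin gene Mgl2 (54.9 to 15.2) were lower and the lipid carrier gene Fabp4 (10.7 to 31.7) higher. In cDC2-like cells Ifnb1 went from 112 to 16.2 and Ccl4 from 4171 to 2142 CPM. Their proliferation genes had a median of -0.27 (percentile 0). It was 0.08 with up to 20% mitochondrial UMIs and -0.06 with the 1 marked cell kept and cells clustered anew. Their Gzmb, a leading NK-like gene, had 147 UMIs in SCR and 2 in KO cells. Misplaced NK cells or doublets are not excluded. In melanoma-like cells all 20 proliferation genes were higher (median 0.61, percentile 100), with Mki67 from 110.1 CPM (95% interval 102 to 119) to 189 CPM (179 to 199) and Top2a from 115 to 199 CPM. There, 17 of 18 MHC class I genes were higher (median 0.24, percentile 99.9), with H2-K1 from 105 to 158 and Tap1 from 21.5 to 37.0 CPM. Of 15 interferon-gamma response genes 12 were higher (median 0.54, percentile 100), such as Igtp (14.3 to 35.7). Of 20 stress genes 19 were higher (median 0.37, percentile 100). Of 6 MHC class II genes, which mark immune cells, 5 were lower (median -0.66, percentile 0), with H2-Eb1 from 101 to 49.2 CPM. Of the cytotoxic list Ccl4 (103 to 158 CPM) and Ccl5 (83.6 to 108) were higher, so immune genes went both ways. Melanoma transcripts were lower (9 of 14, median -0.10, percentile 0.83), with Ptgds from 2193 to 1165 and Cited1 from 92.5 to 54.5 CPM. The largest ratios were in Fgf21 (2.55 to 13.1 CPM), Kit (5.10 to 23.2) and Ccl7 (32.3 to 111), and the smallest in Col28a1 (40.1 to 2.62), Rhox5 (36.5 to 2.48) and Adm (54.8 to 5.79).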

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

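The tests of template amount, of clonotypes of at least 10 reads, of thinned footprint libraries and of crossed splits of libraries were chosen only after the results were seen. Among 70 groups of mice tested for a single value far from the others by Dixon's test, 5 were found, where chance gives about 1 in 20. The largest clonotype of KO mouse 2 held 1.31% of its reads, above the other KO mice. The TRBV17 share reached 7.33% of reads in 1 KO mouse, above the others of its group. The TRBV19 share was 3.09% in 1 KO mouse, below the others. The TRBJ2-3 share was 0.429% in 1 KO mouse, below the others. The TRBJ1-6 share was 0.578% in 1 SCR mouse, below the others.

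The footprint libraries held 14 genes with 0 counts in both libraries of a genotype and at least 50 in both of the other. Read assignment between overlapping gene models by the authors' quantification would give such genes whichever libraries are set against each other. The splits that put 1 library of each genotype on each side gave 7 and 4 genes, on average 0.393 of the number between genotypes. Read assignment cannot be told apart from a loss of footprints in a genotype for these genes, since only 2 such splits exist and both gave some genes but fewer. A difference in their expression between genotypes stays open as untested.

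Mice with KO tumours had more TCRβ clonotypes. A difference in read depth is excluded, since the difference held after thinning to far fewer reads than the lowest total (exact permutation p = 0.0159). Errors in clonotypes of fewer than 10 reads do not account for the difference. It held among clonotypes of at least 10 reads (6494 against 4354, exact permutation p = 0.0159). Errors copied from large clonotypes can reach 10 reads, so sequencing errors as a whole are not excluded. More T cells or more template in the KO samples cannot be told apart from a broader repertoire, because reads carry no molecular identifiers; singletons made up 37.1 and 38.9% (exact permutation p = 0.0635), which decides nothing. A broader repertoire in mice with KO tumours stays open and untested.

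TE fell in more genes than it rose in KO cells, 81.2% of the calls being falls. Lower depth of the KO footprint libraries is excluded, since 77.6% were falls with every footprint library thinned to the lowest total. The scaling between libraries fits as an explanation of the excess, since upper-quartile scaling gave 58.2% falls, although RLE and TMM within each assay gave 75.5 and 75.1%. Under upper-quartile scaling the ribosomal protein medians were -0.49 and -0.39 and that of interferon-stimulated genes 0.72, while the small medians of the mitosis and ligand lists changed sign (0.09 and 0.02). Lower translation of many mRNAs in KO cells stays open as a hypothesis.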

How the results depend on the processing

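Several alternatives were added after the data had been seen: thinned footprint libraries, leaving out genes at 0 footprints in a genotype, clonotypes of at least 10 reads, equal numbers of CDR3s, leaving out the 8% highest doublet scores, the phagocyte sum and leaving out nuORFs in pseudogenes. Where a value below moved, the cause was not tested unless stated. With 2 libraries per group, a fit without a replicate leaves a group with 1 library, which is assumed to vary like the others. No gene called in the full data changed sign under any setting, and of 1231, 574 and 1434 results of named genes in input RNA, footprints and TE, 160, 210 and 516 no longer passed. Planned nuORF alternatives based on TPM were not run. The depth of the KO footprint libraries limits what can be seen for genes with few footprints.

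Genes changed in input RNA (3358) numbered 1193 without a low-count filter, 433 at an absolute log2 fold change of at least 1 (a stricter rule), 2158 with all 8 libraries in 1 fit, and 1031 to 4251 with a replicate left out. In footprints (387) they numbered 1207 with DESeq2, 755 without a filter, 1329 at 1 CPM or more in every library, 100 at a log2 fold change of at least 1, 1483 with all 8 libraries in 1 fit, and 25 to 128 with a replicate left out. With a replicate block, edgeR called 0 in footprints (3495 at an unadjusted p below 0.05) and 363 in TE. In TE (973) they numbered 1722 with DESeq2, 2018 at 1 CPM or more, 235 at a log2 fold change of at least 1, 581 with limma's voom, and 0 to 1187 with a replicate left out. With culture as a replicate block edgeR called 0 in TE (3881 at an unadjusted p below 0.05). Whether replicate numbers pair these libraries is not stated, so the fits with a block cannot be set aside. Of 23 lists, camera called 16 in input RNA, 12 in footprints and 16 in TE; with an estimated correlation it called 0, 0 and 0, by fry 7, 0 and 9 were called, and with the block camera called 16, 10 and 14.

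With mice paired by number 1 to 4, which are not true pairs, the smallest exact p is 0.125, and the differences were 11298 clonotypes, 0.805 nats of entropy, -0.0586 in clonality, 1100 in inverse Simpson index, -9.53 percentage points in the top 100 share and 0.138 amino acids. With a mouse left out, the differences were 10578 to 14357 clonotypes, 0.645 to 0.984 nats, -0.0450 to -0.0711 in clonality, 931 to 1409 in inverse Simpson index, -6.39 to -12.0 percentage points and 0.105 to 0.174 amino acids. The 10 largest clonotypes differed by -1.12 percentage points, CDR3 length weighted by counts by 0.0465, and 11 V and J genes passed by share of clonotypes. Clonotype sharing differed by -6.83 percentage points with equal numbers of CDR3s per mouse. Without pseudogenes 833 KO nuORFs remained.

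In single cells the log2 ratio of the T-like share was -0.44 with up to 20% mitochondrial UMIs, where T-like is a smaller cluster of 63 and 47 cells led by regulatory T-cell genes, and the NK-like cluster (253 and 264 cells) has Cd3e at 461 CPM. It was, for the macrophage-like share, -0.21 at resolution 0.5 and, for the monocyte-like share, 0.24 at resolution 1.5. Jchain in phagocytes turned to -1.17 with up to 20% mitochondrial UMIs. At that setting the medians were 0.0691 for MHC class I in macrophage-like cells, 0.0777 for proliferation and 0.0120 for interferon-stimulated genes in cDC2-like cells, and 0.0715 for cytotoxic genes in phagocytes. With the 1 cell marked as a doublet kept and all cells clustered anew these were 0.0714, -0.0607, 0.0397 and 0.0489. With the 8% highest doublet scores left out, they were 0.0627 for interferon-stimulated and -0.0035 for macrophage genes in cDC2-like cells, 0.0456 for cytotoxic genes in phagocytes and -0.11 for inflammatory cytokines in T-like cells. Of 309 list results, 277 were the same, 12 weaker and 20 stronger.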

Other observations

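The comparisons across assays and of nuORF host genes below, with the test of called hosts, were chosen only after the values were seen, apart from the medians of host RNA. Genes of the cultured cells were also seen in the melanoma-like cells of the tumours, with 1 library per genotype. Adm, which encodes adrenomedullin, fell in KO input RNA (-2.03, SE 0.20) and went from 54.8 to 5.79 CPM in melanoma-like cells. Cited1 fell in KO footprints (-1.66, SE 0.08) and went from 92.5 to 54.5 CPM. Kit fell in input RNA (-0.61, SE 0.07) but went from 5.10 to 23.2 CPM, and the MHC class I list had a median of -0.28 in input RNA of cultured cells and 0.24 in melanoma-like cells. In unnamed cluster 2 proliferation genes had a median of -0.17 (percentile 0), inflammatory cytokines -0.14 (0.005), the macrophage list -0.23 (0) and interferon-stimulated genes 0.09 (99.7).

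Of amino acid CDR3s, 2698 were in all 9 mice. In all 5 KO and no SCR mice were 43, and in all 4 SCR and no KO mice 23. Of all splits into 4 and 5 mice, the real one included, 5 gave as many as the former (highest other 54). As many as the latter came from 102 (highest other 55). Clonotypes of ranks 1 to 20 in a mouse were in a mean of 6.45 of the 8 other mice. Those far down the ranking were in 1.28. Read carry-over between libraries was not tested for any TCRβ result. By share of reads 0 V and J genes passed, so all 100 splits, the real one included, gave as many by definition. By share of clonotypes 11 passed, with at most 0 in other splits.

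A hypothesis was that nuORFs were listed as larger in a genotype because host gene RNA was higher there. In the planned comparison, median log2 fold changes of input RNA differed by 0.02 between KO and SCR hosts. This decides nothing, since both rose and fell. Genes in both lists (125) were left out. Of 466 hosts called in input RNA, 216 (46.4%, 95% interval 41.8 to 51.0) moved against their list (59 KO fell, 157 SCR rose). The other 250 moved with it (113 KO rose, 137 SCR fell). Host RNA is thus excluded as the whole cause for the called hosts, not as a part of it. It stays open for the others, such as KO hosts without an annotated coding sequence (347 of 553 measured). Footprints on hosts had medians of 0.16 for KO (12 rose, 3 fell of 1139) and -0.09 for SCR (2 rose, 46 fell of 1323). The lists were drawn from the same libraries.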
